A study of Triticum aestivum with 4 samples.

How the data were processed

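Developing wheat (*Triticum aestivum*) seed was collected 5 days after anthesis from field-grown plants of 2 genotypes, Domain and RL4452, the parents of a mapping population. Plants stood in rows of 1.47 m in a lattice layout with 3 replications, per the labels' protocols. Messenger RNA was enriched, copied into biotin-labelled cRNA in a single amplification cycle, and hybridised to an Affymetrix wheat array, per the labels' protocols. Each of the 4 arrays holds 1 biological replicate, numbered 1 or 3 within its genotype. Nothing in the labels says that a shared number marks a shared field block or preparation day.

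The deposited values are linear ratios, and RMA is named in the submitters' processing notes. The program version and any step after RMA are not given in the sources used here. In the deposited table the median of each probe set over the 4 arrays lay within 0.002 of a ratio of 1 for 99.5% of the 61290 features, and the ratios ran from 0.0115 to 81.87. The values are thus relative to each probe set's own median. Differences between arrays are kept, and the level of 1 probe set against another is lost. The unit had been assumed to be log2 before the data were examined, so the ratios were log2-transformed before any test. The column medians were ratios of 0.987 and 1.006 in Domain replicates 1 and 3, and 0.998 and 1.007 in RL4452 replicates 1 and 3. Scanner setting files were deposited for each array and, per the file headers, give the fluidics module and hybridization day, which were read only as possible batches. They hold no other measurement used here. No signal over background could be computed, and the number of arrays limits the precision.

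The 111 AFFX control probe sets were left out of the tests, and 61179 probe sets were tested, 64 of them reporter sequences. RL4452 was compared with Domain with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term, 2 arrays per genotype). Calls had a Benjamini-Hochberg adjusted p under 0.05, two-sided. Differences are RL4452 minus Domain on the log2 scale. Because p-values rest on 2 arrays per genotype, they draw on a spread shared across probe sets, with 2.99 prior degrees of freedom. The planned Pearson correlations between arrays were not computed, because division by each probe set's median fixes much of their outcome. The SD of log2 differences between arrays is given in their place. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

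Gene names came from the array's annotation, updated through the gene table of the assembly IWGSC CS RefSeq v2.1, of which no coordinates were used. A single gene symbol was listed for 1273 features, several for 0, and 60017 were not listed. Of the 771 genes, 770 were found in the gene table. A readable symbol or synonym was available for 200 probe sets of 102 genes, and 1073 carried a LOC number alone.

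Gene lists were fixed as 21 name patterns before the data were examined. The patterns were mostly words of gene descriptions, while the tables hold short symbols, so 17 lists matched no probe set even where such genes were present (LTP3, a lipid transfer protein, for example): seed storage proteins, starch synthesis and sucrose cleavage, lipid transfer proteins, pathogenesis-related proteins, resistance-type and receptor kinases, histones, cell cycle, photosynthesis, cytosolic ribosomal proteins, cell wall, hormones, transcription factors, anther and pollen, embryo, aleurone and transfer cells, common reference genes, and transposable elements. These include every list of markers of other tissues. A further 13 lists were drawn from the names in the gene tables after values had been seen. Lists of at least 5 probe sets were tested with limma camera (preset correlation 0.01, two-sided, Benjamini-Hochberg within the fixed and within the added lists). The alternatives were an estimated correlation and fry, which tests whether the members of a list move, on balance, one way.

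Named genes followed a rule fixed before the data were examined. It took the called probe sets with an informative gene name, up to 12 in each direction, or, where none passed, the 10 named probe sets with the smallest p. It also took the smallest-p member of each list with none past the threshold, which was extended to the added lists after values had been seen. The 2 largest called differences in each direction are given too. The rule had planned these only for the case that no probe set was paired with a gene. The test was tried on simulated values for 61179 probe sets with the prior of the genotype comparison, 50 probe sets changed at each size. It recovered 0% of 2-fold, 10% of 4-fold, 64% of 8-fold and 94% of 32-fold changes, and 3 of its 87 calls were false. In a simulation of the list test, the shifted list was called, and 1 unshifted list had an unadjusted p under 0.05. Probe sets were drawn independently there, so it does not show how the test behaves where list members are correlated.

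The alternatives were a replicate block, each array left out in turn, quantile normalization again, centring on array medians, a robust prior, probe sets without shared probes, a treat threshold of 0.5 log2 units, other set tests, 1 probe set per gene, and a count without a test.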

Results

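Transcript levels in whole developing seed 5 days after anthesis were compared between the wheat genotypes RL4452 and Domain, the parents of a mapping population used to study differences in expression level. The data comprised 4 arrays, 2 biological replicates per genotype, with 61179 probe sets tested. Values are log2 ratios to each probe set's own median over the 4 arrays.

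Between the genotypes, 171 probe sets differed, 79 higher and 92 lower in RL4452 (limma, Benjamini-Hochberg adjusted p under 0.05). The called differences were large, but the test itself selects for size. With 2 arrays per genotype it recovered 0% of 2-fold and 10% of 4-fold changes in the simulation. The sizes below thus describe the calls and not the usual difference between the genotypes. The smallest called difference was 3.66-fold, the median was 10.3-fold and the largest 181-fold, and 87 calls exceeded 10-fold (38 higher and 49 lower in RL4452). None of the probe sets with the largest differences has a listed gene. The largest positive difference belonged to a probe set that averaged -5.92 ± 0.44 in Domain and 1.13 ± 0.20 in RL4452 (SD, n = 2), a log2 difference of 7.05 with SE 0.27. The next largest was 6.87. The largest negative differences were -7.50 with SE 0.29 and -7.18 with SE 0.26. For comparison, the median absolute log2 difference over all tested probe sets was 0.17.

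Each array was left out in turn. Without Domain replicate 1 limma called 0 probe sets (3292 at an unadjusted p under 0.05), and without Domain replicate 3 it called 0 (3418 at an unadjusted p under 0.05). Without RL4452 replicate 1 it called 101, and without RL4452 replicate 3, 128. The difference of -7.50 became -7.79 without Domain replicate 1 and -7.21 without Domain replicate 3. These fits had 1 residual degree of freedom, with 2.68 prior degrees of freedom without a Domain array and 4.08 without an RL4452 array.

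**Figure D1:**
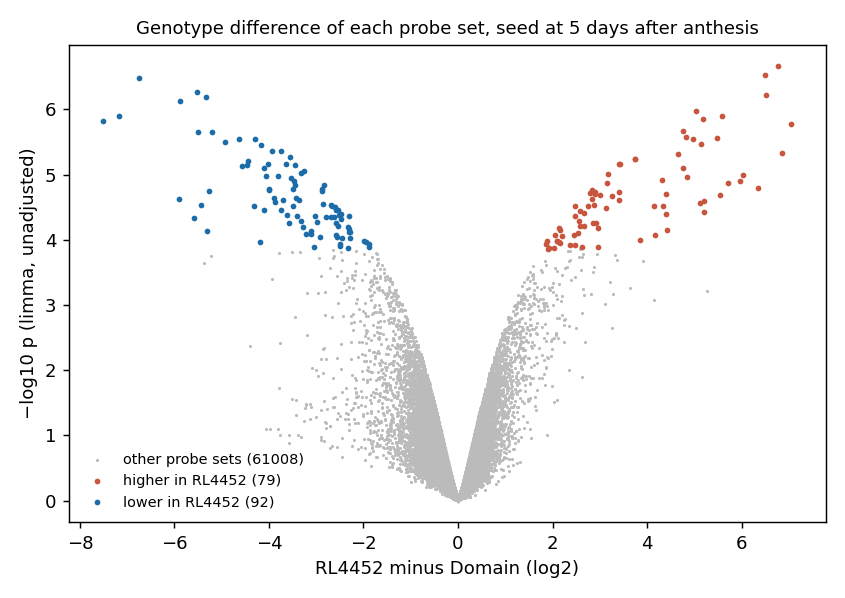
Each point is 1 probe set, with the RL4452 minus Domain difference (log2) on the x axis and -log10 of the unadjusted limma p on the y axis. The 79 calls higher in RL4452 are red, the 92 lower are blue, and no call lies closer to 0 than 1.87 log2 units.

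Of the 171 called probe sets, 2 had a listed gene, both with a LOC number alone, and both were named after their values were seen. A probe set of LOC780602 was 9.97-fold lower in RL4452, averaging 0.89 ± 0.05 in Domain and -2.43 ± 0.14 in RL4452 (SD, n = 2; limma adjusted p = 0.0134). The other probe sets of this gene had differences of -0.84, -0.68, -0.21 and -0.01 and did not pass. LOC100037572 was 5.98-fold lower, with a log2 difference of -2.58 and SE 0.19 (limma adjusted p = 0.0220). This second call was lost after quantile normalization (-2.27, limma adjusted p = 0.0864), without RL4452 replicate 1 (limma adjusted p = 0.0645) and without RL4452 replicate 3 (limma adjusted p = 0.0514). The listed share among calls, 1.17%, was not distinguishable from the 2.08% among all tested probe sets (two-sided Fisher exact p = 0.591).

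No probe set with a readable gene name passed the threshold. The 10 with the smallest p are given as such. For the granule-bound starch synthase Wx-A1 (LOC543395), which makes amylose, the log2 level averaged -1.64 ± 0.51 in Domain and 0.74 ± 0.11 in RL4452 (SD, n = 2). The difference was 2.39 with SE 0.29 and limma adjusted p = 0.0992, and after quantile normalization it was 2.72 with adjusted p = 0.0436. The catalase CAT1 had a difference of -1.67 with SE 0.22 (limma adjusted p = 0.120), while its other probe set had -0.11. TaGlu1a (LOC780595), a beta-glucosidase, had a difference of 1.38, and GAPN, a non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase, had -0.80. The gibberellin 20-oxidase GA20ox1D (LOC543325), a step of gibberellin synthesis, had 0.74. The gene lgul (LOC542984) had -1.11 for the probe set named by the rule, -0.74 without Domain replicate 1, and -0.37 for the other. The others were the ATI amylase and trypsin inhibitor genes LOC543281 at -2.96 and LOC543286 at -2.57 and -2.65, and the avenin-like gene avnla (LOC780582) at -2.47. Without Domain replicate 3 LOC543281 had -1.94 and avnla -1.57, and without RL4452 replicate 1 the second LOC543286 value was -1.66. Limma adjusted p of the 10 ranged from 0.0992 to 0.580.

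The fixed list of grain inhibitors and indoline-type proteins held 5 probe sets of 4 genes, serpins and a thionin, both defence-related or inhibitor proteins of the grain. Its members had a median of -0.34, with 4 lower and 1 higher in RL4452. None passed the threshold over all probe sets, and none did adjusted over the list alone. The list had adjusted p = 0.0195 in limma camera but adjusted p = 0.394 with an estimated correlation. The thionin gene THI1.3 (LOC543413) had the smallest p, at -1.57 with SE 0.47, and at -0.89 without Domain replicate 3. Its other probe set had -1.49, while the serpin probe sets had -0.34, -0.09 and 0.10. The larger values of the list thus belonged to 1 gene. With 1 probe set per gene the median was -0.22 over 4 members, too few to test. The list's median was -0.61 without Domain replicate 1. Without Domain replicate 3 it was -0.08 (limma adjusted p = 0.152), and without RL4452 replicate 1 it was -0.28 (limma adjusted p = 0.166). The other fixed lists with members were too small to test. The heat shock list held hsp16.9A (LOC543277) at -4.05 with SE 1.86, where the Domain arrays averaged 3.36 ± 4.13 (SD, n = 2), and at -1.13 without Domain replicate 1 and -6.97 without Domain replicate 3. The dehydration and cold list held COR410 at -0.17, and at -0.090 without Domain replicate 3. The redox list held 2 probe sets of the gene PER1 (LOC543108), at 0.36 and -0.15, the first at 0.61 without Domain replicate 1 and 0.12 without Domain replicate 3.

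Among lists drawn up after values had been seen, amylase inhibitors and thionins had the largest shift of the 9 tested. All 11 probe sets, of 7 genes, were lower in RL4452, also after quantile normalization or median-centring, with a median of -2.11. In 10 of the 11 both Domain arrays lay above both RL4452 arrays. Chance separates 16.7% of independent probe sets in that direction. These 11 come from 7 genes on the same arrays and may move together, so the count cannot be judged against that share. Adjusted over the list alone 8 passed the threshold, and 0 did over all probe sets. The list had adjusted p = 2.37e-09 in limma camera and adjusted p = 0.640 with an estimated correlation. The 17 probe sets of prolamins and avenin-like proteins, the storage proteins of the endosperm, had a median of -0.41, with 15 lower in RL4452. Their limma camera adjusted p was 0.000720, and the adjusted p was 0.640 with an estimated correlation. Without Domain replicate 1 the median of this second list was -0.73, and without probe sets with shared probes -0.70. Without Domain replicate 3 it was -0.08 (limma adjusted p = 0.0879), and that of amylase inhibitors and thionins was -1.21 (limma adjusted p = 5.55e-06). These lists were chosen on the same arrays and are not independent evidence of a direction. The THI1.3 probe sets of the fixed list are also members of the amylase inhibitor and thionin list.

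**Figure D2:**
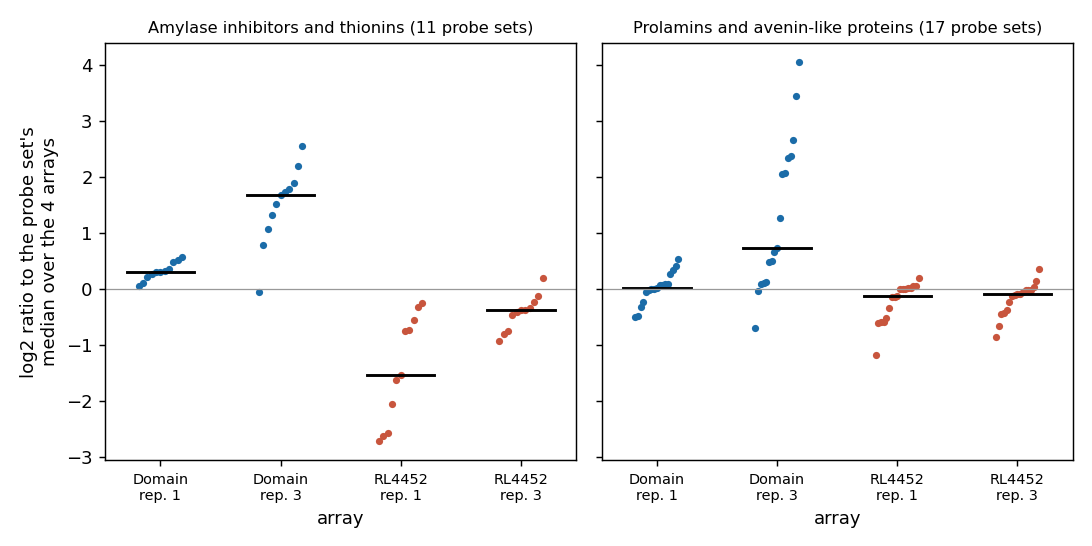
Points are probe sets of 2 lists in each of the 4 arrays, the y axis is the log2 ratio to the probe set's 4-array median, and black lines are medians over the list. The amylase inhibitor and thionin medians were 0.30 and 1.68 in the Domain arrays and -1.54 and -0.38 in the RL4452 arrays, while the prolamin median stood apart in Domain replicate 3, at 0.73.

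The remaining 7 tested lists did not pass in limma camera with all arrays and probe sets. Tubulins had a median of -0.22 over 10 probe sets, which was -0.084 without Domain replicate 1, with Tubb5 (LOC543261) at -0.56. Translation factors and ribosomal proteins had -0.18 over 9, with eIF4E (LOC543485), a cap-binding initiation factor, at -0.55, which was -0.20 without Domain replicate 1 and -0.90 without Domain replicate 3. Redox enzymes had -0.15 over 12, histones H2A and H2B 0.09 over 18, and late embryo and dehydration proteins -0.11 over 10. The histone median was 0.036 without Domain replicate 3, 0.021 without RL4452 replicate 3 and 0.14 without RL4452 replicate 1, and that of redox enzymes was -0.077 after quantile normalization. Adjusted over its list alone, 1 redox probe set passed, the CAT1 one at -1.67, which did not pass over all probe sets (limma adjusted p = 0.120). Photosynthesis genes had a median of 0.02 over 36 probe sets of 6 genes, but most of these probe sets belong to rbcL (LOC100049018). With 1 probe set per gene the median was -0.26 (limma camera adjusted p = 0.130). The median over all 36 lay below 0 without either Domain array (-0.024 and -0.012) and without RL4452 replicate 3 (-0.037), and serpins had -0.09 over 5. Some passed in limma camera when an array was left out. Without Domain replicate 1 these were serpins (-0.32) and late embryo proteins (-0.24), both with adjusted p = 0.0165, while without Domain replicate 3 their medians were 0.0014 and 0.20. Translation factors passed without Domain replicate 3 (-0.61, limma adjusted p = 0.00356) and without RL4452 replicate 1 (-0.35, limma adjusted p = 0.0205), while their median was -0.075 without Domain replicate 1 and -0.037 without RL4452 replicate 3. Redox enzymes passed without RL4452 replicate 1 (-0.40, limma adjusted p = 0.0205), while their median was 0.054 without RL4452 replicate 3. Lists under 5 probe sets are described only. The 4 gibberellin 20-oxidase probe sets had a median of 0.49. The 2 of GA20ox1D passed adjusted over the list alone, but over all probe sets their limma adjusted p was 0.692 and 0.496. With 1 probe set per gene, or without probe sets with shared probes, the median of the list was 0.24. The 4 raftin probe sets had -0.11, which was -0.037 without Domain replicate 1, and the 1 without shared probes had 0.23. The 2 starch synthesis probe sets both passed adjusted over the list alone, on opposite sides of 0 (Wx-A1 at 2.39 and AGP-S at -0.66). Over all probe sets their limma adjusted p was 0.0992 and 0.832. Since the added lists were drawn up after values had been seen, passing over such a list alone is not independent evidence. The 2 heat-inducible ones had a median of -2.42, which was -0.69 without Domain replicate 1 and -4.15 without Domain replicate 3.

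The genotypes stood little or no further apart than replicates of 1 genotype, depending on the measure. The SD of log2 differences across probe sets was 0.457 between the Domain arrays and 0.499 between the RL4452 arrays, against 0.509 to 0.618 between arrays of different genotype. The scaled median absolute deviation, which extreme probe sets move little, was 0.344 between the Domain arrays and 0.347 between the RL4452 arrays. Between arrays of different genotype it was 0.308, 0.313, 0.365 and 0.413. The ratio of the mean between-genotype SD to the mean within-genotype SD was 1.15, and this description carries no p-value.

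As a measure of RNA quality, the ends of control transcripts were compared. The 3' minus 5' log2 difference of the wheat control transcripts (7 probe set pairs) had a median of 0.40 in RL4452 replicate 3, against -0.22 in RL4452 replicate 1 and 0.00 in both Domain arrays. For the poly-A spike-ins (12 probe set pairs), bacterial transcripts added to the sample, it was 1.25 in RL4452 replicate 3, -0.59 in RL4452 replicate 1 and -0.23 in both Domain arrays. These pairs are repeats of the transcripts dap, lys, phe and thr, so they are not 12 separate controls. Spike-ins do not come from seed and do not report the quality of its RNA. All are relative to each probe set's 4-array median.

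**Figure D3:**
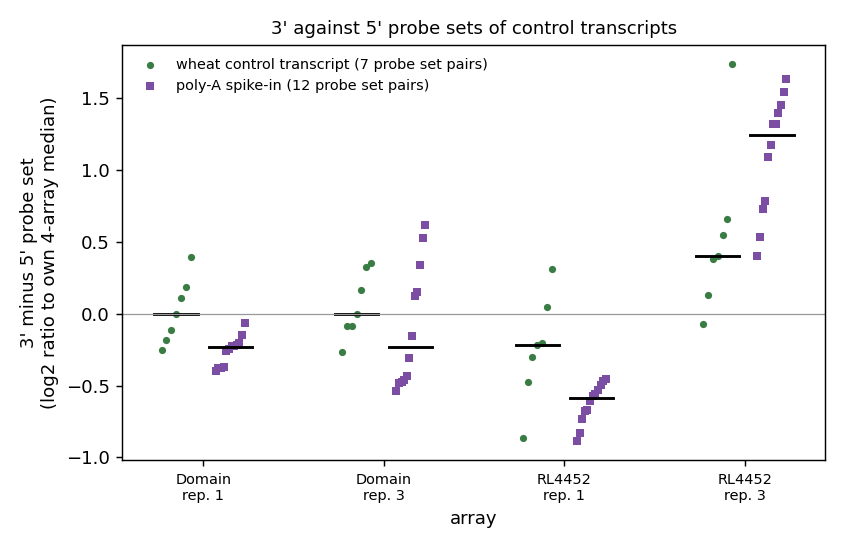
Points are pairs of 3' and 5' probe sets of 1 control transcript in each of the 4 arrays, the y axis is their log2 difference (3' minus 5'), each relative to its 4-array median, and black lines are medians. RL4452 replicate 3 has the highest median in both kinds of control, 0.40 for wheat control transcripts and 1.25 for poly-A spike-ins. Several poly-A points are repeats of the same transcript.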

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

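The gap count, the added lists and 1 probe set per gene were chosen after seeing the data. With a replicate block limma called 0 probe sets, 0 higher and 0 lower (4555 at an unadjusted p under 0.05). The numbers are not stated to pair samples, and the replicate differences of both genotypes correlated at 0.143 across probe sets. In replicates 1 and 3 the poly-A spike-ins had medians of 0.50 and -0.92 in Domain and 1.33 and -0.86 in RL4452, and the 18S rRNA probe set 0.75 and -1.68, and 2.04 and -3.12. Leaving out each array gave 0 to 128 calls, 0 to 60 higher and 0 to 68 lower, a lone array being assumed to vary like the other genotype's. A gap over 1 log2 unit between genotypes, untested, held for 640 probe sets, 278 higher and 362 lower, against at most 70 in the other 2 splits of the arrays. Those gave 0 calls. At an unadjusted p under 0.05 the genotype split had 3578, the split by replicate number 3602 and the crossed one 1380, non-overlap was 32.4%, 39.0% and 27.2% (33.3% by chance), and 3 splits are too few for a share under 0.05. Other counts of calls ran from 131 (treat) to 171 (robust prior). With an estimated correlation or fry, grain inhibitors (-0.34, adjusted p = 0.394 and 0.330), prolamins (-0.41) and amylase inhibitors and thionins (-2.11, both 0.640 and 0.633) lost their call. Over arrays left out, medians ran from -0.61 to -0.081 for grain inhibitors, -0.73 to -0.078 for prolamins, -0.32 to 0.0014 for serpins, -0.037 to 0.020 for photosynthesis, -0.24 to 0.20 for late embryo proteins and -0.40 to 0.054 for redox enzymes. With 1 probe set per gene tubulins (0.0087) and photosynthesis (-0.26) changed sign. Lists not called gained a call 9 times, among them translation factors with the block (adjusted p = 0.0499) and, without probe sets with shared probes, translation factors (0.0103), redox enzymes (0.0170) and tubulins (0.0418). The 6 named probe sets past the threshold lost it with the block or without either Domain array, and 1 of them, LOC100037572, also after quantile normalization or without either RL4452 array.

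Not run were the dim filter, the intensity trend and the highest-mean probe set, since the ratios hold no levels. Each array had its own hybridization day, replicates 1 before replicates 3. The 1 fluidics module with both genotypes held Domain replicate 3 and RL4452 replicate 1, and a module block left no residual degrees of freedom. Between those arrays the medians were -0.67 for grain inhibitors, -3.53 for amylase inhibitors and thionins and -0.87 for prolamins. These arrays held each list's highest and lowest medians, so module stays untested.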

Other observations

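Of the tests below, those on the spread of an array, on 5' ends and on opposite directions were chosen after the result was seen. The values of 2 gliadin probe sets, singled out after they were seen, were high in 1 array. Gliadins are monomeric storage proteins of the endosperm. The gamma-gliadin gene LOC543214 had a probe set at 4.05 in Domain replicate 3 against 0.33, -0.61 and -0.43 in Domain replicate 1, RL4452 replicate 1 and RL4452 replicate 3. The alpha-type gliadin gene LOC543211 had 3.45 against -0.23, 0.20 and -0.38. The other 6 gliadin probe sets with a readable name ran from -0.035 to 1.26 in Domain replicate 3, including 0.10 and 0.73 for LOC543214. No enrichment was tested. In that array 43 probe sets were more than 4-fold higher than in each other array, these 2 gliadin probe sets among them. The others with a readable name were also grain proteins. They were the avenin-like gene LOC100125692, with probe sets at 2.66 and 2.07, and the ATI gene LOC543281 at 2.55. A further probe set of LOC100125692 had -0.70 in that array. Some of the 43 had no listed gene but came from the same transcript clusters as named gliadin probe sets. All members of the 43 with a readable name belong to the prolamin or the amylase inhibitor and thionin list. This pattern and the shifts of those lists are thus not separate observations.

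In Domain replicate 1, 101 probe sets were more than 4-fold higher than in each other array, up to 73.4-fold. The small heat shock gene hsp16.9A (LOC543277) was the 1 member with a readable name, at 6.28 against 0.44 in Domain replicate 3, -0.75 in RL4452 replicate 1 and -0.63 in RL4452 replicate 3. A wider spread of the array would also give low values, and 0 probe sets were more than 4-fold lower there. A part played by genotype stays open. Domain replicate 3 exceeded the RL4452 mean by a median of 0.38 over the members (upper quartile 0.86). Members were chosen as lower there than in Domain replicate 1, so the small size of this value excludes nothing. Domain replicate 3 lay above both RL4452 arrays in 66.3% of members, against 33.4% of all tested probe sets. The choice of members treats those arrays alike, but members may move together, so this share was not tested. A condition of that plot or seed sample may account for the pattern, and was not tested.

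In RL4452 replicate 3, 992 probe sets (1.62%) were more than 2-fold lower than in each other array. Loss of 5' ends in the seed RNA alone is argued against by the poly-A spike-ins, whose highest 5' minus 3' value in that array was -0.40. Less labelled product from 5' ends on that array stays open: the spike-in median was -1.25, but the wheat control median was only -0.40, and probe positions within transcripts were not used here. No biological explanation was tested.

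The called differences were large, with a median of 10.3-fold. In the 49 transcript clusters with a call and another sequence, the largest call of each had a median size of 3.46. The other sequences, called ones included, had a median of 0.30 in its direction (upper quartile 1.40). In 8 clusters they moved at least 50% as far, and in 73.5% they moved the same way. Whether a change of that size, or a smaller one, was shared by all sequences stays open. The ratios hold no levels, so sequences near background cannot be told from unchanged ones. The largest call was also picked for its size. Sequence differences between the parents at the probes and expression of 1 gene copy cannot be told apart without values of single probes. Of 5 clusters with calls on several sequences, 1 had opposite directions (4.14 and -2.99) and 4 the same. Genotype, which the design names, stays open as a source of either.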
